A study of Homo sapiens with 4 samples.

How the data were processed

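RNA was sequenced from SJSA-1, an established human osteosarcoma cell line, in 2 control and 2 ZNF217 knockdown samples. Per the labels, total RNA was extracted with the PureLink kit and libraries were built at a university genomics core by its standard method. The reagent used for the knockdown, the strand setting of the counting and the gene annotation are not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

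The deposited counts are whole reads per gene, 1 column per library, not normalized. Per the submitters' processing notes, Trimmomatic, HISAT2, Subread and DESeq2 were used with the GRCh38 genome, without versions. The authors also deposited a signal per library, named as TPM, whose columns sum to 10 times what TPM columns sum to. These values equal count divided by gene length, scaled to that sum, with a largest difference of 5.2e-10. A second deposited signal is the authors' mean normalized count of each gene, made by DESeq2 per the file headers. The deposited log2 fold changes, with their standard errors, are control over knockdown, and the deposited p-values and adjusted p-values come from the same DESeq2 table by the authors, per the file headers. The sources used here do not state which libraries entered that table. It was not used for any test.

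The counts of 20024 genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with TMM scaling and no covariate. The edgeR low-count filter with its defaults (a minimum count of 10 and a minimum total of 15) left 12965 genes. Each p was two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A gene's CPM was its count scaled by the TMM-scaled library total. Fold changes are knockdown over control, and log2 values are those of the edgeR fit unless DESeq2 1.42.0 is named. DESeq2 and limma 3.58.1 served as alternatives. Gene positions came from GENCODE release 29 on GRCh38 and were found for 19981 genes. Genes whose reads a close copy could share are named as uncertain. The same holds for overlapping and antisense genes, since the strand setting is unknown.

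Before the data were examined, 35 gene lists with 824 symbols were written, of which 821 were found in the table. The 34 lists with at least 5 tested members were compared with all other tested genes by camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation and fry were run beside it. For lists called by camera, the count of passing members is also given adjusted over the list alone. The genes named were ZNF217, then up to 10 genes in each direction with an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between groups, then the members of each list with the smallest p, and 6 genes fixed by name. Because no gene passed the adjusted threshold, that selection was repeated with an unadjusted p under 0.05, a choice made after the values were seen. Further list members named as examples, and the members of the NRF2 list, were also chosen after their values were seen.

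Totals ranged from 21466327 to 24487126 counts per library. A gene with 0 counts has an upper limit of 3 counts, which is 0.117 to 0.139 CPM. These limits cover counting error only. The tests were checked on simulated counts of 12965 genes, 200 of them changed. With one spread for both groups, edgeR called 11% of the genes changed 2-fold and 92% of those changed 4-fold. With the common spread of each group as measured here, edgeR called none, while DESeq2 called 19% and 94%. Of the 132 DESeq2 calls, 19 were genes that had not been changed. With those spreads and no gene changed, both called 0 genes. Each simulation gave every gene of a group the same spread, while spread differs between genes in the data, so these rates need not carry over. With one spread for both groups, camera with the preset correlation recovered 100% of 20 lists shifted by 0.7 on the log2 scale. It called 0 of 200 unchanged lists. With an estimated correlation it recovered 0%. Those simulated genes varied independently of each other, so this says nothing about lists whose members vary together.

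Alternatives fixed before the data were examined were other scaling factors, no or a stricter low-count filter, DESeq2, limma on counts or on TPM, the replicate number as a block, a threshold of 0.01, and each library left out. Limma with sample quality weights and a correction of each library for GC content were added after the data were seen. Figures were drawn with matplotlib 3.10.9.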

Results

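Messenger RNA levels were measured in SJSA-1 cells with or without knockdown of ZNF217, a zinc finger transcription factor of the chromosome band 20q13. Each group held 2 libraries. The control libraries had 21466327 and 24487126 counts, and the knockdown libraries had 24428774 and 23217521. The labels place the study in the context of AKT signaling and metastasis in osteosarcoma, so genes of those processes were among the lists examined.

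ZNF217 (ENSG00000171940, chromosome 20, 53567065 to 53609907 on the minus strand of GRCh38) was measured at 66.2 and 73.4 CPM in the control libraries and at 37.6 and 31.9 CPM in the knockdown libraries. The group means were 69.8 ± 5.15 and 34.7 ± 4.03 CPM (SD, n = 2 each), so that knockdown cells held 49.7% of the control level. The log2 fold change was −1.01 with a standard error of 0.20. Its adjusted p was 0.207 by edgeR and 0.0115 by DESeq2. Both knockdown libraries lay below both controls, the direction their labels state.

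By camera with its preset correlation, knockdown cells held more transcript of interferon-stimulated genes and of cholesterol synthesis genes, and less of integrin, motility and matrix protease genes. With an estimated correlation the adjusted p was 0.62 for each of these lists, and by fry it was 0.132, 0.132 and 0.226. IFIT3, an antiviral interferon-stimulated gene, was 12.2-fold higher, at 18.2 ± 2.8 CPM in control and 223 ± 8.38 CPM in knockdown (SD, n = 2 each). SPP1, which encodes the bone matrix protein osteopontin, was 11.3-fold higher, with 11.5 ± 4.46 and 129 ± 5.47 CPM. The osteoblast markers, the list that holds SPP1, were not called, with a median log2 fold change of −0.24 (camera adjusted p = 0.815). Of its 11 tested members 2 were higher and 2 lower in both knockdown libraries than in both controls. TIMP3, an inhibitor of matrix metalloproteinases, was 12.9-fold lower, with 246 ± 60.9 CPM in control and 19 ± 2.82 CPM in knockdown.

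No single gene passed the adjusted threshold of edgeR: 0 genes were called higher and 0 lower, and the lowest adjusted p was 0.11. At an unadjusted p under 0.05, 857 genes were higher and 833 lower, where 648 in all would be expected by chance if both groups had the same spread. DESeq2 called 230 genes higher and 267 lower, 215 and 236 of them by 2-fold or more. The control libraries differed from each other far more than the knockdown libraries did, and control replicate 2 stood apart. Across genes, which are not independent replicates, log2 CPM of control replicate 1 correlated at 0.94 with control replicate 2 and at 0.962 with each knockdown library, while the knockdown libraries correlated at 0.993. The biological coefficient of variation between the controls was 0.39, against 0.0776 between the knockdown libraries, and leaving out control replicate 1 or control replicate 2 raised the calls to 3710 and 2374 higher genes and 3729 and 2183 lower genes, under the assumption that a lone control varies like the knockdown pair.

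**Figure D1:**
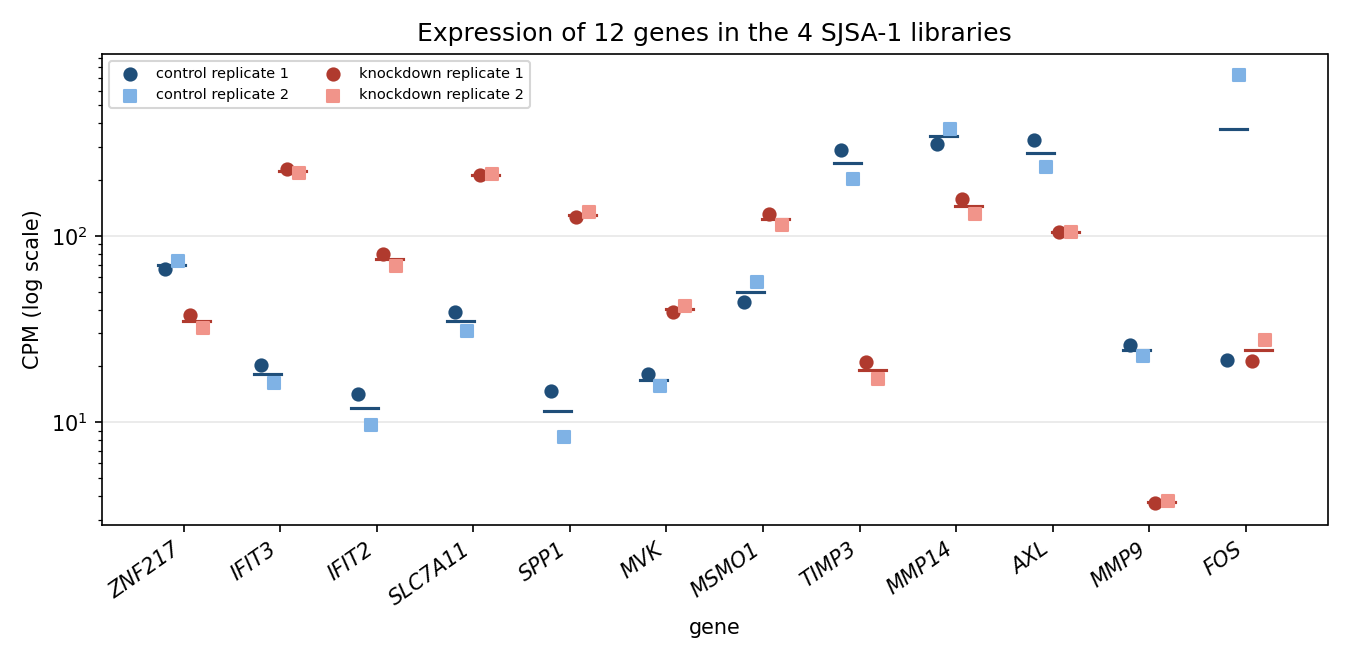
CPM on a log axis of 12 genes in each of the 4 libraries, with circles and squares for replicates 1 and 2, and a short line at each group's mean. IFIT3 has a mean of 18.2 ± 2.8 CPM in control and 223 ± 8.38 CPM in knockdown (SD, n = 2 each), while FOS lies at 725 CPM in control replicate 2 and between 21.2 and 27.7 CPM in the other libraries.

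Some of the genes with the largest differences are given as values. On the higher side were C3AR1, TNIP3, TDO2, ATP6V0D2, ZSCAN31, VIT, CALHM5, IFIT3 and TRIM16L, with log2 fold changes from 3.55 to 5.21. C3AR1, the receptor of a complement fragment, was low in control, at 0.587 ± 0.306 CPM, and at 22 ± 0.0577 CPM in knockdown. TDO2, a tryptophan-degrading enzyme, was at 1.15 ± 0.80 and 20.7 ± 0.854 CPM. TRIM16L has a close paralog, TRIM16, and reads may have been shared between the pair, so its 11.7-fold difference is uncertain. On the lower side were B4GALNT4, INHBA, TIMP3, NID1, PDGFB, PODXL, ZNF853, DACT1 and COL22A1, with log2 fold changes from −2.72 to −4.13. The basement membrane protein NID1 was at 87.4 ± 48.1 CPM in control and 7.92 ± 0.942 CPM in knockdown, and the sialomucin PODXL at 123 ± 61.5 and 12.4 ± 0.549 CPM. The controls disagreed for INHBA, an activin subunit, at 38 and 307 CPM, against 13.7 and 11.3 CPM in knockdown. Without control replicate 2 the log2 fold change was −1.61 for INHBA, −2.55 for B4GALNT4, −1.78 for ZNF853, −1.51 for COL22A1 and −0.98 for PDGFB, against −3.79, −4.13, −3.16, −2.72 and −3.33 with all libraries. The DESeq2 adjusted p of INHBA was 0.0625, while those of C3AR1 and TIMP3 were 1.25e-23 and 1.50e-28.

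Interferon-stimulated genes rose as a list, with a median log2 fold change of 1.31 over 33 tested members. The knockdown libraries lay above both controls for 28 members and below both for 0. Over all 12965 genes tested, they lay above both controls for 3296 and below both for 2964. Thus 48.3% of all tested genes lay apart, where 33.3% would be expected by chance if all libraries varied alike. Adjusted over the list alone, 19 members passed, all higher, and 0 passed over all genes tested. IFIT2 was 6.25-fold higher, at 11.9 ± 3.19 and 74.6 ± 7.81 CPM, and IFIT1 3.7-fold higher, at 16.2 ± 2.9 and 60.2 ± 5.06 CPM. ISG15, a ubiquitin-like modifier, was at 231 ± 132 CPM in control and 289 ± 38.8 CPM in knockdown, with overlapping libraries. The camera adjusted p was 7.48e-16 with the preset correlation, and 0.62 with an estimated correlation.

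Cholesterol and fatty acid synthesis genes also rose as a list, with a median of 0.63 over 29 members and an adjusted p of 4.91e-06 (adjusted p = 0.62 with an estimated correlation). Of these members 21 were higher in both knockdown libraries than in both controls and 1 was lower. Adjusted over the list alone, 7 were higher and 1 lower. MVK and MSMO1, enzymes of the mevalonate and late sterol pathways, were 2.41-fold and 2.44-fold higher, at 40.6 ± 2.18 and 122 ± 11.5 CPM in knockdown. HMGCS1, the synthase at the start of the mevalonate pathway, was at 64 ± 18.7 and 134 ± 1.2 CPM. The lower member was INSIG1, a brake on sterol synthesis that is itself induced by sterol-responsive transcription, at 45.9 ± 10.1 CPM in control and 18.2 ± 1.92 CPM in knockdown.

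Integrins, motility genes and matrix proteases fell as a list, with a median of −0.62 over 32 members and an adjusted p of 1.22e-05 (adjusted p = 0.62 with an estimated correlation). Of the members 19 were lower in both knockdown libraries than in both controls and 1 was higher, and 5 passed adjusted over the list alone, all lower. Without control replicate 2 the median was −0.38 (adjusted p = 0.00514). MMP9, a gelatinase, was 6.54-fold lower, at 24.3 ± 2.51 and 3.71 ± 0.0592 CPM. MMP14, a membrane-bound collagenase, was 2.37-fold lower, at 341 ± 44.3 and 144 ± 17.8 CPM. TIMP3 in this list inhibits such proteases. Mesenchymal regulators fell as well, with a median of −0.41 over 24 members and an adjusted p of 0.00254 (adjusted p = 0.636 with an estimated correlation). Of these 10 were lower in both knockdown libraries and 3 were higher, and adjusted over the list alone 3 passed, all lower. Among all genes tested, 48.3% were lower or higher in both knockdown libraries than in both controls. Among the mesenchymal regulators FN1, fibronectin, was 2.83-fold lower, at 1957 ± 647 and 693 ± 92.6 CPM. The call of that list ended without control replicate 2, where its median was −0.22. Without control replicate 1 its median was −0.77.

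YAP-TEAD targets fell with a median of −0.39 over 20 members. Of these 8 were lower in both knockdown libraries and 2 were higher, beside 48.3% of all tested genes that were lower or higher. Adjusted over the list alone 5 passed, all lower. The receptor tyrosine kinase AXL was at 279 ± 64.2 and 104 ± 0.342 CPM. The adjusted p of this list was 0.0237 with the preset and 0.62 with an estimated correlation, and it was 0.51 without control replicate 1 (median −0.23) and 0.062 without knockdown replicate 2 (median −0.31). Corepressor partners of ZNF217 fell with a median of −0.40 over 16 members, 11 of them lower in both knockdown libraries than in both controls, and 0 passed adjusted over the list alone or by DESeq2. HDAC1, a histone deacetylase, was at 169 ± 5.05 and 109 ± 0.15 CPM. The adjusted p of these partners was 0.00452 (adjusted p = 0.62 with an estimated correlation) and 0.0925 without control replicate 2 (median −0.17). Chondrocyte markers had a median of −1.09 over 6 members and an adjusted p of 0.0388 (adjusted p = 0.62 with an estimated correlation). Of these members 5 were lower in both knockdown libraries and 1 was higher, and adjusted over the list alone 3 were lower and 1 higher. The higher member was the transcription factor gene SOX5, at 0.271 ± 0.122 and 1.71 ± 0.234 CPM. The call ended without control replicate 1 (median −1.04, adjusted p = 0.0559), without control replicate 2 (median −1, adjusted p = 0.0941) and without knockdown replicate 2 (median −1.05, adjusted p = 0.0582). It also ended after GC correction (median −0.94, adjusted p = 0.0931) and without a low-count filter, where the median was −0.53 (adjusted p = 0.145).

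The controls differed within the called lists. Medians of control replicate 2 minus control replicate 1 were 0.35 for interferon-stimulated genes, −0.13 for cholesterol synthesis, 0.34 for integrins and proteases, 0.40 for mesenchymal regulators, −0.48 for YAP-TEAD targets, 0.08 for corepressor partners and 0.67 for chondrocyte markers. For the other 5 called lists they were 1.34 for immediate early genes, 1.41 for NF-kB genes, −1.29 for DNA replication genes, −0.26 for G2/M genes and 0.48 for ribosomal protein genes. Immediate early genes, which serum and stress induce, had a median of 0.07 against control replicate 1 and −1.46 against control replicate 2. FOS was at 21.4 and 725 CPM in the controls, and EGR1 at 22.2 and 519 CPM. NF-kB and inflammatory genes had medians of 1.06 and −0.13 against the same libraries, DNA replication genes −0.28 and 1.09, G2/M genes −0.29 and 0.06, and cytosolic ribosomal protein genes −0.07 and −0.58. All 40 ribosomal protein genes, which have many pseudogenes, were higher in control replicate 2 than in control replicate 1. Adjusted over the list alone, 2 immediate early genes passed, both lower, 1 NF-kB gene passed, higher, and 0 passed in each of the other lists. The adjusted p of these lists, in the order named, was 1.22e-05, 0.0388, 0.0388, 0.0388 and 1.22e-05 with the preset correlation, and 0.678, 0.759, 0.895, 0.745 and 0.759 with an estimated correlation. Without control replicate 2 the adjusted p was 0.715 for immediate early genes and 0.156 for ribosomal protein genes, and DNA replication genes had a median of −0.28 (adjusted p = 0.00522). Without control replicate 1 it was 0.414 for NF-kB genes and 0.66 for G2/M genes. Calls also ended for G2/M genes without knockdown replicate 1 or 2 (adjusted p = 0.082 and 0.165), with total counts (0.0803) and with the replicate number as a block (0.0666). They ended for DNA replication genes without knockdown replicate 2 (adjusted p = 0.0582), with total counts (0.0803), without a low-count filter (0.0673) and after GC correction (0.0627), and for NF-kB genes with total counts (0.0803), without a filter (0.0673) and with a stricter one (0.0521).

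**Figure D2:**
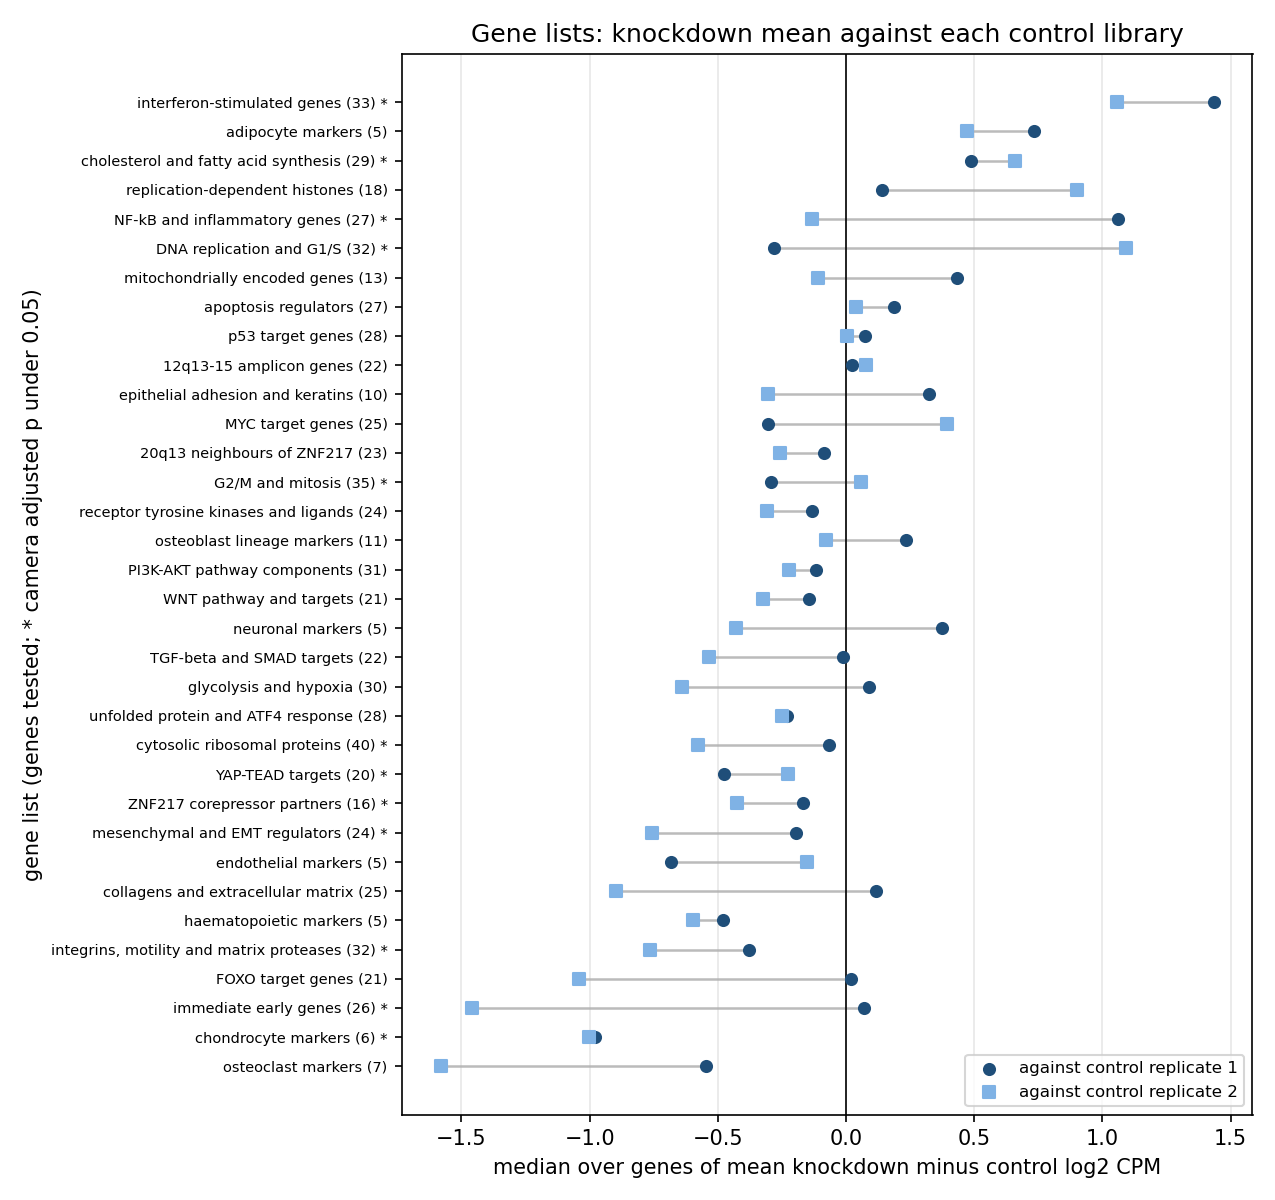
Median over each list's tested genes of the mean knockdown log2 CPM minus that of control replicate 1 (circles) or control replicate 2 (squares), for 34 lists, with a star at a camera adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes lie at 1.44 and 1.06, while immediate early genes lie at 0.07 and −1.46.

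Since edgeR called no gene of any kind, its lack of calls in the AKT pathway says nothing about that pathway. Neither of the pathway's lists was called by camera. The 31 tested components of the PI3K-AKT pathway had a median of −0.26 (camera adjusted p = 0.0951), which was −0.12 without control replicate 2 and −0.17 without knockdown replicate 2, and FOXO targets, which AKT signaling represses, a median of −0.79 over 21 members (adjusted p = 0.0951). The FOXO list passed without control replicate 1 (median −1.05, adjusted p = 0.00401) and with the replicate number as a block (median −0.60, adjusted p = 0.0391), but its median was 0.06 without control replicate 2 (adjusted p = 0.899). DESeq2 called 1 of the pathway's components, PIK3R3, at 3.37 ± 0.599 and 9.37 ± 1.44 CPM (adjusted p = 0.0249), and 3 of the FOXO targets, with TXNIP higher and KLF6 and KLF2 lower (adjusted p = 0.0426, 0.00665 and 0.0182). AKT1 was at 258 ± 16.9 CPM in control and 243 ± 12 CPM in knockdown, and AKT2 at 71.4 ± 19.8 and 85.1 ± 0.978 CPM. ERBB3 had 9, 7, 13 and 9 counts, and CDH1 had 0, 0, 0 and 1, too few to test. Transcript levels do not measure the phosphorylation of AKT. The list of 20q13 neighbours, which holds the knocked-down ZNF217 itself, had a median of −0.17 (camera adjusted p = 0.0951). That median was −0.27 without control replicate 1 and −0.09 without control replicate 2. The potassium channel gene KCNG1 of this list was at 116 ± 7.43 and 44.4 ± 3.61 CPM. Genes of the 12q13-15 amplicon had a median of −0.01 and p53 targets a median of −0.01, both with an adjusted p of 0.935.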

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

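The tests on sampling noise, on control replicate 2 alone, on blood cell markers, on the knockdown reagent and on the authors' table were chosen only after the result was seen. The tests on GC content and on another cell line were set beforehand, that is before their own results were seen. The GC correction itself was added only after the data had been seen.

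Interferon-stimulated genes had a median log2 fold change of 1.31, called by camera with the preset correlation but not with an estimated correlation (adjusted p = 0.62) or by fry (adjusted p = 0.132). A difference that came from control replicate 2 alone is argued against by a median of 1.44 over the same genes against control replicate 1. A GC trend of the libraries as the whole cause is argued against by a median of 1.23 after correction of each library. Blood cells in the knockdown samples were tested by the summed CPM of 14 haematopoietic markers, whose lowest knockdown value was 0.633 of the highest control value. However, CD68 alone made up 80.7% of the sum, so the test cannot exclude a small share of blood cells. Whether the CD68 signal came from the line itself was not tested. Of the 5 markers tested, 2 were higher in both knockdown libraries than in both controls, among them LCP1 at 2.4 ± 0.325 CPM in control and 6.35 ± 0.844 CPM in knockdown, and 3 were lower, and each passed adjusted over the list alone while 0 passed over all genes tested. A response to the reagent, and not to the loss of ZNF217, cannot be told apart from the effect of ZNF217, because the median of 1.31 comes from the only contrast the labels name, and either may be the source.

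The 2 control libraries differed more than the knockdown libraries. A GC trend is argued against as the whole cause, since the coefficient of variation between the controls was 0.374 after the correction, against 0.39 before it. The value of 0.39, with counting noise already taken off, restates the difference and is no separate test of sampling noise. A chi-square of the counts, expected in proportion to library totals, was 153 per degree of freedom between the controls (12735 genes). Between the knockdown libraries it was 8.46 (12927 genes). Counting noise alone would make the chi-square about equal to its degrees of freedom. Both pairs exceeded that mark, so passing it does not single out the controls, and the totals were not TMM-scaled. The values show only that counting noise was not the whole of the difference within either pair. Another cell line in one control is argued against by 0 genes with at least 10 CPM in one control and 0 counts in the other. A different growth state of the cultures stays open and untested, and could also lie behind the immediate early genes.

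The authors' deposited table gave a mean above 0 for 765 genes that had no count in any of the 4 libraries, up to a mean of 114.1. The authors' deposited table gave a mean of 0 for 932 genes that did have counts, up to 257 over the 4 libraries. These values, found in columns that no comparison used, are consistent with statistics made from other or further libraries. Which libraries those were stays open.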

How the results depend on the processing

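Limma with sample quality weights and the GC correction were chosen after the data were seen. Interferon-stimulated genes, cholesterol synthesis genes and the integrin, motility and protease list passed camera's preset test with every other scaling and filter, with the block, after GC correction and with each library left out, the only 3 of the 12 called lists to do so. Camera was not run with DESeq2 or limma, and 0 lists passed with an estimated correlation and 0 by fry. Over libraries left out the medians of those 3 ranged from 1.12 to 1.49, 0.49 to 0.65 and −0.77 to −0.38. Of the lists not called, 9 passed under some alternative: FOXO, MYC and TGF-beta targets, glycolysis, epithelial genes (without control replicate 1, median −0.57, adjusted p = 0.0423), collagens, mitochondrial genes, histones and osteoclast markers. Genes called higher and lower, from 0 and 0, numbered 16 and 3 without a low-count filter (2-fold or more: 16 and 3), 230 and 267 by DESeq2 (215 and 236), and 69 and 123 with quality weights (67 and 122). They ranged over single libraries left out from 12 to 3710 and from 3 to 3729 (12 to 1327 and 3 to 1354), with a lone library assumed to vary like the other group. The other alternatives gave 0, apart from the block. With the replicate number as a block they were 160 and 124 (158 and 123). The deviations of same-numbered libraries from their group means correlated at −0.03 across genes. Yet replicate 2 minus replicate 1 rose with GC content in both groups, with a Spearman correlation of 0.28 in control and 0.454 in knockdown. Whether the numbers pair the libraries therefore stays open. The cause of the differing numbers of calls was not tested. ZNF217 passed by DESeq2 at −1.03, and ranged from −1.13 to −0.89 over libraries left out, passing without control replicate 1 or 2 (adjusted p = 3.17e-15 and 1.45e-10) and not without knockdown replicate 1 or 2 (adjusted p = 1 for both). Total counts alone shifted the median of all genes by 0.114 and TPM plus 0.1 by 0.113.

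Directions turned as follows, and their cause was not tested. For apoptosis regulators only the test's direction turned, without control replicate 1 or knockdown replicate 1, while the median stayed between 0.03 and 0.19. Over libraries left out, medians ranged from −1.05 to 0.06 for FOXO targets, −0.81 to 0.12 for collagens and extracellular matrix, −0.28 to 1.09 for DNA replication, −0.30 to 0.05 for G2/M genes, −1.47 to 0.07 for immediate early genes, −0.12 to 0.08 for p53 targets, −0.31 to 0.39 for MYC targets, −0.68 to 0.09 for glycolysis, −0.57 to 0.37 for epithelial genes, −0.14 to 1.06 for NF-kB genes, −0.29 to 0.24 for osteoblast markers, −0.03 to 0.10 for 12q13-15 genes, −0.12 to 0.43 for mitochondrial genes, −0.64 to 0.33 for haematopoietic markers and −0.44 to 0.38 for neuronal markers. Log2 fold changes ranged from −0.01 to 0.56 for AKT2, −4.43 to 0.13 for EGR1, −4.90 to 0.19 for FOS, −0.18 to 1.07 for ISG15 and −0.08 to 0.40 for TKT. AKT1 was 0.03 with total counts and 0.04 after GC correction. Where a list's test changed direction, its median was 0.15 for p53 targets with the stricter filter and −0.04 after GC correction, 0 for epithelial genes and 0.06 for apoptosis regulators with the block, −0.14 for osteoblast and 0.72 for haematopoietic markers without a filter, and −0.17 for neuronal markers with total counts. Medians alone changed sign for p53 targets (0.13), MYC targets (0.06), epithelial genes (0.10) and 12q13-15 genes (0.12) with total counts, for MYC targets (0.03), p53 targets (0.03) and 12q13-15 genes (0.01) with the block, for epithelial (0.02) and 12q13-15 genes (0.03) with the stricter filter, for epithelial (0.09) and mitochondrial genes (−0.01) after GC correction, and for neuronal markers (1.22) without a filter. By fry the test's direction turned for p53 targets (−0.01), WNT genes (−0.28), osteoblast markers (−0.24) and haematopoietic markers (−0.62), whose medians are those reported. Depth limits genes with few counts, such as CDH1 with 0 or 1.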

Other observations

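The test of NRF2 targets was chosen only after the result was seen: 21 of the 30 genes of the list had been looked at before it was written.

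A list of 30 genes that the oxidative stress factor NRF2 is known to induce was examined. Adjusted over the list alone 17 were higher in knockdown and 1 was lower, and 0 passed over all genes tested. Most members were listed with their values in view, so counts over all 30 describe the list and are no test. With an estimated correlation the camera p of all 30 was 0.0695. SLC7A11, the cystine transporter, was 6.05-fold higher, at 35 ± 5.79 CPM in control and 212 ± 1.85 CPM in knockdown (SD, n = 2 each). SQSTM1, the autophagy receptor p62, was at 438 ± 71 and 1440.0 ± 172 CPM, and GCLC, which makes the first step of glutathione synthesis, at 31.9 ± 5.17 and 87.2 ± 4.95 CPM. HMOX1, heme oxygenase, was at 24.6 ± 1.44 and 51 ± 8.14 CPM. Of the 30 genes 28 were higher in both knockdown libraries than in both controls, 1, the transporter gene ABCC1, was lower, and 1, the transketolase gene TKT, overlapped. Reads may have been shared among AKR1C1, AKR1C2 and AKR1C3, and between TRIM16 and TRIM16L. These members are therefore uncertain and not separate evidence.

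A hypothesis is that NRF2 targets differ from other genes as a list, which may reflect more NRF2 activity in knockdown cells. Because most of the list was chosen with its values in view, the test was limited to the 9 members not looked at beforehand. These gave a camera p of 0.0159 with the preset correlation and a p of 0.278 with an estimated correlation, with a median log2 fold change of 0.45, against 1.01 for all 30. Of these 9 genes 7 were higher in both knockdown libraries and 1 was lower. Adjusted over the 9 alone, 1 passed as higher and 0 as lower. Among the 7 was PGD, of the pentose phosphate pathway, at 231 ± 31.3 and 456 ± 19.8 CPM. The 9 include AKR1C3, at a log2 fold change of 1.71, whose reads may be shared with AKR1C1 and AKR1C2, both looked at beforehand. The 9 were thus not wholly held out, and the test was not run without AKR1C3. The hypothesis therefore rests on the preset correlation and on a set that holds AKR1C3. A response to the reagent was not tested for this list.

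A total of 240 genes in the authors' deposited table had an adjusted p under 0.05, 172 of them higher and 68 lower in knockdown. Of the 233 tested here, 205 (88%) had the same direction as in the authors' deposited table. Over all 12579 genes compared, called or not, 60.2% had the same direction, and the correlation of the log2 fold changes across genes, which are not independent replicates, was 0.447. Of the 497 genes called here by DESeq2, 78 were called there. The deposited table may share libraries with the counts used here, so this is not an independent comparison. For ZNF217 the authors' deposited table gave a log2 fold change of control over knockdown of 0.56 with an adjusted p of 0.622.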
